A study of Homo sapiens with 17 samples.

How the data were processed

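Total RNA of HEK293T cells was depleted of ribosomal RNA and sequenced as stranded libraries by the dUTP method, with 1 of 2 kits, per the labels' protocols; which library was made with which kit is not given in the sources used here. The 17 libraries fall into 6 groups by cell line, time and auxin, per the labels. The submitters' processing notes name STAR 2.7.3a, DESeq2 without a version, and the builds hg38 and dm6, with no role or order for any of them. The annotation release, the counting tool and its strand setting are not given in the sources used here. Which tests, lists and alternatives would be used was fixed before the data were examined, apart from those named below as chosen later.

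The signal values, normalized counts per gene and library, were made by the authors by division of read counts by 1 size factor per library, as the deposited values show. They cover the 6 untreated libraries, and 0 columns of values per library were left without a sample. Reads were recovered by division by the step of each library, its smallest value above 0, and 100% of the values were whole within 0.001 reads. The step of INTS1-AID library 2 lies close to 1, and its reads were recovered in the same way. The log2 values are fold changes that the authors deposited per comparison, and the p-value columns hold their p-values and adjusted p-values, per the file headers. Score columns hold the authors' calls and mean normalized counts, rounded to whole numbers, per the file headers. The authors also deposited a standard error for the comparison of the cell lines, and transcript lengths in bases. For the 11 libraries of the 4 h and 12 h series only such comparison columns were used, so their depth is unknown.

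The table of the cell lines has headers that name another assay, yet its fold changes are those of its own INTS1-AID and parental counts. Its adjusted p-values are not Benjamini-Hochberg values over its own genes, whereas those of the other comparisons are. The direction of the 4 h fold change was checked against a deposited log2 expression column. With auxin over no auxin, and 2 libraries in the denominator, the median error was 0.0013 on the log2 scale over 1085 genes, against 0.146 or more for the other readings. The 12 h direction was taken as the same, since the fold changes of both times correlate across 10700 genes (Pearson's r = 0.85); no column settles it by itself. Of 14538 genes, 14523 have identifiers in GENCODE v29, which gave GC content, and 14510 lie on the same chromosome there.

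For the untreated lines the planned count test gave way to limma, because the deposited unit is a normalized count. Genes with a mean normalized count of at least 10 were kept (13293), log2(normalized count + 1) was fitted with limma 3.58.1 (trend and robust) in R 4.3.3, and calls were made at a Benjamini-Hochberg FDR of 0.05. Alternatives were pseudocounts of 0.1 and 10, no filter, a mean of at least 50 reads, each library left out, the replicate number as a block, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, library totals, an FDR of 0.01, and a log2 change of at least 1. Alternatives chosen after seeing the data were edgeR with TMM, removal of each library's GC trend (lowess, span 0.3), genes of chromosome 5 left out, the authors' own calls, and camera without parental library 3.

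For 4 h and 12 h, genes were called at an adjusted p under 0.05 of the authors' deposited table, where the label DESeq2 in the text refers to the authors' test. The difference between 12 h and 4 h was tested with a Wald z test, chosen after seeing the data, from the log2 changes and the standard errors that their p-values imply, with Benjamini-Hochberg adjustment. The implied standard errors were checked on the cell line table, where the largest relative difference from the listed ones was 5.42e-14. For 12 genes at 4 h and 8 at 12 h the p is listed as 0, and these entered at a z of 38.

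The 24 gene lists, fixed by name, were Integrator subunits, the PP2A core, the integrated stress response (ATF4 targets), eIF2α kinases and RNA sensors, the unfolded protein response, the interferon response, NF-κB targets, immediate early genes, termination and elongation factors, Pol II snRNA, Pol III small RNA, replication-dependent histones, p53 targets, heat shock, AhR targets, cholesterol synthesis, cell cycle, SRF and cytoskeleton genes, ribosomal proteins, mitochondrial genes, embryonic kidney, adrenal and neural genes, and markers of blood, colon and fibroblasts. For the untreated lines they were tested with limma's camera (correlation 0.01), with an estimated correlation, and with fry. For the auxin effects each median was placed among 10000 random lists matched in 20 bins of mean expression, and limma's cameraPR (correlation 0.01 or 0.05, and on ranks), chosen after seeing the data, gave the adjusted p. Benjamini-Hochberg adjustment ran over the 20 lists with enough genes. Named genes were, per comparison, the 8 with the largest rise and the 8 with the largest fall (5 each for the difference) among those with an adjusted p under 0.05, a mean of at least 100, groups that do not overlap where libraries are given, and a named symbol. To these were added up to 4 members of each list that passed, and INTS1, INTS11, ATF4, DDIT3 and EIF2AK2 always.

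On simulated data for the untreated lines, limma (13285 genes) recovered 98% of 100 genes changed 2-fold and 71% of 100 changed 1.5-fold, with 11 false calls (6.11%). On the same simulation edgeR (13288 genes) recovered 98% and 71% with 12 false calls (6.63%), and DESeq2 (14538 genes) recovered 98% and 83% with 34 false calls (15.8%). For the difference between times, the Wald test (14460 genes) recovered 98% of 200 genes changed 2-fold, with 9 false calls (4.39%). cameraPR called 2.5% of 200 simulated lists without a shift and 100% of those with one. These rates hold for the simulated settings only. The simulated counts held no GC trend and no library that stands apart. The Wald simulation drew values with the standard errors that the test used, and changed only genes with small ones. The simulated lists were random genes, so correlation between list members was not simulated. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.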

Results

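Expression was measured by stranded RNA sequencing of total RNA depleted of ribosomal RNA, in 17 libraries of HEK293T cells, a human embryonic kidney line. In the INTS1-AID line, INTS1 carries a homozygous miniAID tag, a degron through which auxin directs the tagged protein to degradation. INTS1 is a scaffold subunit of Integrator, a complex that cleaves nascent RNA polymerase II (Pol II) transcripts, forms the 3' ends of small nuclear RNA (snRNA) and ends transcription early on many protein-coding genes. The libraries form 6 groups. These are untreated INTS1-AID cells (3 libraries), untreated parental cells (3), INTS1-AID cells of the 4 h series with 500 µM auxin (3) or without it (2), and INTS1-AID cells of the 12 h series with 500 µM auxin (3) or without it (3). The untreated INTS1-AID libraries 1, 2 and 3 held 39321998, 31051182 and 26952038 reads in genes. Parental libraries 1, 2 and 3 held 27962916, 35413737 and 26294938. For the other 11 libraries the values are the authors' comparisons, and their depth is unknown. No label says that replicates are separate cultures, so the p-values measure the spread between these libraries, which may be technical.

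The comparison of untreated INTS1-AID with untreated parental cells asks whether the tagged line differs from its parent before any auxin. INTS1 itself had a normalized count of 5530 ± 1708 (SD, n = 3) in parental and 3956 ± 215 (n = 3) in INTS1-AID cells. Its log2 change of -0.44 did not pass the test (limma adjusted p = 0.298), and is -0.21 without parental replicate 3 and -0.24 with the GC trend of each library removed. Its mRNA does not show the level of the protein. NWD2 (ENSG00000174145), on chromosome 4, rose the most, from 6.16 ± 2.17 to 253 ± 19.04 normalized counts (SD, n = 3 in each group, log2 change 5.19, limma adjusted p = 0.000432). RAB11B, a GTPase of recycling endosomes, rose from 284 ± 62.5 to 984 ± 73.7 (log2 change 1.81), and CPPED1, a phosphatase, from 94.2 ± 23.1 to 332 ± 22.2 (log2 change 1.83). ROBO2, an axon guidance receptor, fell from 199 ± 20.5 to 53.8 ± 10.3 (log2 change -1.88), and EYA1, a transcriptional coactivator of kidney and ear development, from 558 ± 76.2 to 172 ± 15.7 (log2 change -1.69). Other genes with large rises were ST8SIA4, a polysialyltransferase on chromosome 5 (log2 change 1.91), CNKSR2, a scaffold of Ras signalling (1.56), LRATD2 (1.24), the progesterone receptor PGR (1.16) and the variant U1 gene RNVU1-6 (1.23), whose reads can come from near-identical copies. Other genes with large falls were ABCB6, a porphyrin transporter (log2 change -1.60), LOXL1, which crosslinks elastin (-1.58), the cadherin FAT3 (-1.56), ZC3H12B (-1.21), ZNF329 (-1.10) and the histone gene H2BC8 (-1.09).

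Chromosome 5 held 84.96% of the genes that rose. That share is 32.2% without parental replicate 3 (466 of 1447), 51.8% with the GC trend of each library removed and 38.1% of the 21 genes with a log2 change of at least 1. Of 592 tested genes of chromosome 5, 209 rose and 0 fell, against 37 that rose and 49 that fell among the 12701 tested genes elsewhere (odds ratio 187, Fisher's exact test over genes, two-sided p = 4.62e-257; genes are not independent replicates). The median log2 change of chromosome 5 was 0.52, 95.1% of its genes lay above 0, and the highest median of another chromosome was 0.05, on chromosome 4. The median level of chromosome 5 minus that of the other chromosomes was 0.52 ± 0.01 on the log2 scale in INTS1-AID libraries (SD, n = 3) and -0.0022 ± 0.0961 in parental ones (n = 3), with each INTS1-AID library above each parental one. Genes of chromosome 5 that rose included PPP2CA, the catalytic subunit of protein phosphatase 2A (log2 change 0.95), the mitotic cyclin CCNB1 (0.79), the ribosomal protein genes RPS23 (0.68) and RPS14 (0.61), the RNA helicase MTREX of the nuclear exosome (0.65), CCNG1 (0.62) and the ATF4 target STC2 (0.46). Chromosome 5 genes showed no such shift between cells with and without auxin, with medians of -0.02 at 4 h and -0.05 at 12 h in the authors' deposited table.

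**Figure D1:**
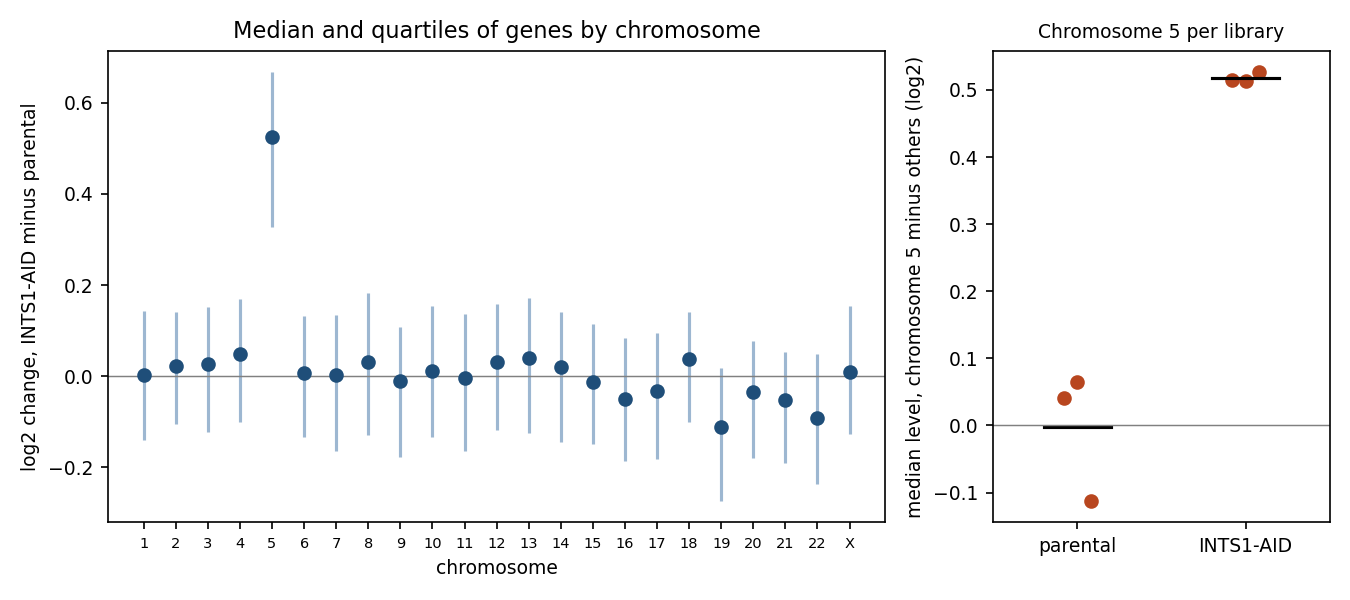
Log2 change between untreated INTS1-AID and parental cells by chromosome (points, medians over genes; bars, quartiles), and, per library, the median log2 level of chromosome 5 genes minus that of other genes (points, libraries; lines, group means). Chromosome 5 has a median of 0.52, and the 3 INTS1-AID libraries sit above 0.5.

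Among the fixed gene lists, 2 genes of the integrated stress response list rose (of 39 measured), the asparagine synthetase gene ASNS (log2 change 0.53, from 3608 ± 294 to 5182 ± 86.7, SD, n = 3) and STC2. Adjusted over the list alone, 6 rose. ATF4, the transcription factor of that response, had a log2 change of 0.32 (limma adjusted p = 0.0393), and DDIT3, which encodes CHOP, one of -0.14 (limma adjusted p = 0.595). EIF2AK2, which encodes the double-stranded RNA kinase PKR, had a log2 change of -0.03, and INTS11, the endonuclease of Integrator, one of -0.08; neither passed the test. The value of INTS11 became 0.09 with the GC trend of each library removed and 0.05 without parental replicate 3. By camera, the integrated stress response list lay higher than other genes (median log2 change 0.13, adjusted p = 0.00376). So did Pol II snRNA (20 measured, median 0.53, adjusted p = 9.22e-05), replication-dependent histones (48 measured, median 0.21, adjusted p = 3.65e-06) and ribosomal proteins (43 measured, median 0.23, adjusted p = 1.25e-11). Without parental replicate 3 the medians of snRNA and histones are 0.26 and 0.13. None of these calls holds with an estimated correlation between genes: adjusted p = 0.418 with an estimated correlation for the stress response and ribosomal protein lists, and adjusted p = 0.481 with an estimated correlation for snRNA and histones. Of single members, RNVU1-6 rose among snRNA (3 when adjusted over the list alone), and H2BC15 rose (log2 change 0.41) and H2BC8 fell among histones (1 rose and 2 fell when adjusted over the list alone). RPS23 and RPS14 rose among ribosomal proteins (12 when adjusted over the list alone). Of the aryl hydrocarbon receptor (AhR) targets, the quinone reductase gene NQO1 rose (log2 change 0.64) and the monooxygenase gene CYP1B1 fell (-0.55; 1 rose and 2 fell of 8 when adjusted over the list alone). Of kidney, adrenal and neural genes, the neurofilament gene NEFL rose (0.43; 1 rose and 3 fell of 12 when adjusted over the list alone). Median and test differed in sign, with no call, for the Integrator list (median -0.0042), and mean and median for the eIF2α kinase and RNA sensor list (median -0.03, mean 0.02) and the cytoskeleton list (median 0.0020, mean -0.11).

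In all, limma called 295 of 13293 tested genes at an FDR of 0.05, 246 higher and 49 lower in INTS1-AID cells, and each of the 295 has groups that do not overlap. Such groups were found for 4080 genes (30.7% of those tested, against 10% by chance). Parental library 3 stood apart from the other parental libraries along GC content (Spearman rho 0.77 across genes between its deviation and GC), and single libraries move the count. It is 2432 without parental replicate 3 (1447 higher and 985 lower; 59.5% higher) and 1 without parental replicate 1, against 271 without parental replicate 2. It is 1, 3 and 4 without INTS1-AID replicates 1, 2 and 3. The split of 83.4% higher moves to 61.3% of 1207 genes when the GC trend of each library is removed. The authors' deposited table holds 806 genes at an adjusted p under 0.05, 63.5% of them higher.

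The comparison at 4 h asks which RNA levels change with 4 h of auxin, which directs the tagged INTS1 to degradation. No parental cells with auxin are among the samples. Effects of auxin itself therefore cannot be told apart from those of INTS1 loss, for any gene here or at 12 h. INTS1 mRNA itself fell by 0.18 on the log2 scale in the authors' deposited table (DESeq2 adjusted p = 0.0123). Among genes with a mean count of at least 100, the largest rises in the authors' deposited table were those of CCDC80, a secreted matrix protein (ENSG00000091986, log2 change 6.48), DIO3, the deiodinase that inactivates thyroid hormone (5.80), RPL3L, a muscle paralogue of a ribosomal protein (5.15), and the AP-1 subunit FOSB (5.03). CRISPLD2 (log2 change 4.95), SOCS1, an inhibitor of cytokine signalling (4.83), the transcription factor SNAI1 (4.66) and the Ras-related RASD1 (4.49) followed in the authors' deposited table. The largest falls among such genes in the authors' deposited table were smaller: PAQR8 (log2 change -1.31), the transcription factor TFAP4 (-1.27), the kinase CAMKK1 (-1.18), SLFN5 (-1.16), the helicase DHX35 (-1.14), CCDC71 (-1.12), the cap methyltransferase PCIF1 (-1.10) and ZC3H6 (-1.05). Immediate early genes, which respond to stimulation without new protein synthesis, rose together, 32 of 39 higher and 0 lower in the authors' deposited table (35 higher when adjusted over the list alone, median log2 change 1.84). Among them were ARC (4.21), FOS (3.96) and IER3 (4.86) in the authors' deposited table, the last with a mean count of 11.

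Integrator genes moved in both directions at 4 h. In the authors' deposited table INTS6L rose by 2.09 on the log2 scale, NABP1 by 2.09, INTS6 by 1.85 and INTS2 by 0.73, whereas INTS11 fell by 0.24 (DESeq2 adjusted p = 0.00261). Of 20 Integrator subunits, 9 rose and 3 fell in the authors' deposited table (the same numbers when adjusted over the list alone, median log2 change 0.08). HEXIM1, the inhibitor of the elongation kinase P-TEFb, rose by 2.48 on the log2 scale in the authors' deposited table, while CDK9, the kinase itself, fell by 0.58, CCNT2 by 0.48 and CPSF4 by 0.46. Of 29 termination and elongation factors, 4 rose and 12 fell in the authors' deposited table (6 and 13 when adjusted over the list alone).

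Of 40 genes of the integrated stress response list, 17 rose and 8 fell at 4 h in the authors' deposited table (18 and 11 when adjusted over the list alone), with a median log2 change of 0.10. The transcription factor genes ATF3 (log2 change 2.38), DDIT3 (2.22) and CEBPB (1.303) and the eIF2α phosphatase subunit PPP1R15A (1.39) rose the most in the authors' deposited table. ATF4 mRNA fell by 0.15 on the log2 scale (DESeq2 adjusted p = 0.00202) and EIF2AK2 by 0.14 (DESeq2 adjusted p = 0.0370) in the authors' deposited table. Of 15 eIF2α kinases and RNA sensors, 3 rose and 4 fell in the authors' deposited table (the same numbers when adjusted over the list alone; median -0.08, mean 0.14, test lower). They included in the authors' deposited table DHX58 (log2 change 2.57), EIF2AK3 (0.30) and MAVS (0.24). Of 17 genes of the unfolded protein response, 7 rose and 1 fell in the authors' deposited table (the same numbers when adjusted over the list alone). HERPUD1 (log2 change 0.78), MANF (0.73), DNAJB9 (0.66) and CRELD2 (0.45) were the highest of them in the authors' deposited table. The interferon response list had 5 of 20 genes higher and 0 lower at 4 h in the authors' deposited table (5 higher when adjusted over the list alone), IRF1 (log2 change 1.76) and IFI6 (1.12) among them.

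Of AhR targets, 6 of 8 rose and 0 fell at 4 h in the authors' deposited table (7 rose when adjusted over the list alone). CYP1A1 (log2 change 2.63), CYP1B1 (2.02), ALDH3A1 (1.60) and TIPARP (0.82) were the highest of these in the authors' deposited table. Of kidney, adrenal and neural genes, 8 of 14 rose and 0 fell in the authors' deposited table (the same numbers when adjusted over the list alone). The neurofilament genes NEFH (log2 change 3.71) and NEFM (1.20), NES (1.81) and SOX2 (0.90) were among them in the authors' deposited table. Of p53 targets, 10 of 21 rose and 4 fell in the authors' deposited table (the same numbers when adjusted over the list alone). The cell cycle inhibitor CDKN1A (log2 change 2.42), PLK3 (2.31), GADD45A (1.52) and POLH (1.14) rose in the authors' deposited table. Pol II snRNA rose at 14 of 25 genes and fell at 0 in the authors' deposited table (the same numbers when adjusted over the list alone, median log2 change 0.43), as with RNU5A-1 (1.15). Copies of these genes share reads, so single values are uncertain. Replication-dependent histones moved the other way in the authors' deposited table, with 28 of 48 lower and 3 higher (29 and 3 when adjusted over the list alone, median log2 change -0.27). H2AC15 (log2 change -0.67) and H3C14 (-0.64) were the lowest of those that passed in the authors' deposited table. The list of cytoskeleton genes and targets of the transcription factor SRF rose at 6 of 11 and fell at 0 in the authors' deposited table (the same numbers when adjusted over the list alone). CCN2 (log2 change 2.16), CCN1 (1.77), TAGLN (0.96) and FLNA (0.84) were the highest in the authors' deposited table. CCN1 and CCN2 also belong to the immediate early list, so the results of these lists are not independent.

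Cell cycle genes split 9 higher to 10 lower of 29 at 4 h in the authors' deposited table (the same numbers when adjusted over the list alone). CCNE1 (log2 change 1.22), CCNE2 (1.15), RRM2 (1.05) and CCND1 (1.02) were higher in the authors' deposited table. Cholesterol synthesis genes split 6 to 3 of 19 (IDI1 0.74), heat shock genes 3 to 0 of 14 (BAG3 0.43) and NF-κB targets 3 to 1 of 9 (TRAF1 1.77) in the authors' deposited table, each with the same numbers when adjusted over the list alone. Ribosomal protein genes split 0 to 3 of 43 in the authors' deposited table (0 to 0 when adjusted over the list alone; RPL13 -0.12). Of the Pol III small RNA list (6 measured) and the PP2A core (4 measured), 0 passed in the authors' deposited table by the adjusted p and when adjusted over the list alone. Of the lists for other cell types too small to test, CORO1A of the blood list rose by 1.54 and CDX2 of the colon list by 0.56 on the log2 scale in the authors' deposited table. Of these lists 2 genes each were measured, of the fibroblast list 1, and of the mitochondrial list 0.

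At an adjusted p under 0.05 the authors' deposited table held 5553 of 14479 genes at 4 h, 2774 higher and 2779 lower. With a log2 change of at least 1 in size the authors' deposited table held 801, of which 771 were higher. Among genes with a mean count of at least 100, 31.0% of those under 10 kb were higher and 13.97% lower, and of those over 100 kb, 14.7% were higher and 32.4% lower in the authors' deposited table. By cameraPR on the authors' deposited table, 10 of 20 lists differed from other genes at 4 h. Immediate early genes (adjusted p = 3.69e-49), Integrator subunits (adjusted p = 9.87e-07), histones (adjusted p = 4.42e-06, lower) and AhR targets (adjusted p = 6.70e-06) came first. The others by cameraPR were kidney, adrenal and neural genes (adjusted p = 9.15e-05), the integrated stress response (adjusted p = 0.000970), p53 targets (adjusted p = 0.00603), cytoskeleton genes (adjusted p = 0.0119), Pol II snRNA (adjusted p = 0.0167) and the unfolded protein response (adjusted p = 0.0458). With a correlation between genes of 0.05 in place of 0.01, the last 2 no longer pass (cameraPR adjusted p = 0.0993 and 0.136). On ranks, cameraPR loses the Integrator list (adjusted p = 0.103), the integrated stress response (adjusted p = 0.115) and p53 targets (adjusted p = 0.159), and gains the interferon response (adjusted p = 0.0165) and ribosomal proteins (adjusted p = 0.0125, lower). The values of single libraries of these groups were not used here, so no correlation between genes was estimated and no replicate could be left out.

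The comparison at 12 h asks the same after 12 h of auxin. INTS1 mRNA had a log2 change of -0.16 (DESeq2 adjusted p = 0.278) in the authors' deposited table. CCDC80 (log2 change 7.66), RPL3L (7.41) and DIO3 (7.01) were again at the top of the authors' deposited table among genes with a mean count of at least 100, followed by FRG2B (6.86), the synaptic immediate early gene ARC (6.60), RASD1 (6.29), the nerve growth factor receptor gene NGFR (6.03) and CRISPLD2 (5.75). Falls were deeper than at 4 h in the authors' deposited table, with PLEKHA7, a junction protein (log2 change -2.46), TSPAN18 (-2.20), the deubiquitinase USP44 (-2.14) and CUX2 (-2.04). The kinase MAP2K6 (log2 change -2.02), EVI5L (-1.98), the synaptic scaffold SHANK2 (-1.95) and RTN4RL1 (-1.94) followed in the authors' deposited table. Pol II snRNA rose at 21 of 25 genes and fell at 0 in the authors' deposited table (the same numbers when adjusted over the list alone). Their median log2 change was 1.82, with RNU5B-1 (2.68), RNU1-2 (2.64) and RNU5F-1 (2.60) among the highest in the authors' deposited table. Histone genes were higher at 44 of 48 and lower at 1 in the authors' deposited table (45 and 1 when adjusted over the list alone, median log2 change 0.65), among them H2BC8 (1.45), H2BC15 (1.29) and H2AC21 (1.25).

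Of the Pol III small RNA list, 3 of 6 genes rose at 12 h in the authors' deposited table (4 when adjusted over the list alone): RNU6-2 (log2 change 1.80), RNU6ATAC (1.24) and RN7SK (0.40). Of the interferon response list, 12 of 20 genes rose and 1 fell in the authors' deposited table (the same numbers when adjusted over the list alone, median log2 change 0.65). IRF7 (log2 change 2.61), IFI6 (2.41), IFITM1 (1.71) and IRF1 (1.68) were the highest of those named in the authors' deposited table. Of eIF2α kinases and RNA sensors, 3 of 15 rose and 4 fell in the authors' deposited table (the same numbers when adjusted over the list alone; median -0.16, mean 0.11, test lower). The RNA helicase gene DHX58 had a log2 change of 3.31 in the authors' deposited table, EIF2AK4 one of -0.68 and EIF2AK2 one of -0.44 (DESeq2 adjusted p = 0.00355). Of the integrated stress response list, 15 of 40 rose and 9 fell in the authors' deposited table (16 and 10 when adjusted over the list alone). ATF3 (log2 change 2.12), CEBPB (1.97), DDIT3 (1.61) and PPP1R15A (1.48) were the highest in the authors' deposited table. ATF4 had a log2 change of -0.08 (DESeq2 adjusted p = 0.496) in the authors' deposited table. The unfolded protein response had 7 of 17 genes higher and 1 lower in the authors' deposited table (the same numbers when adjusted over the list alone; HERPUD1 1.33).

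Immediate early genes rose at 35 of 39 and fell at 1 at 12 h in the authors' deposited table (36 and 1 when adjusted over the list alone, median log2 change 2.08), with FOSB (5.09), FOS (4.88) and GADD45B (4.47). Integrator subunits rose at 10 of 20 and fell at 1 in the authors' deposited table (10 and 2 when adjusted over the list alone). INTS6L (log2 change 2.23), NABP1 (1.99), INTS6 (1.35) and INTS15 (listed as C7orf26, 0.63) were higher and INTS11 was lower (-0.44, DESeq2 adjusted p = 0.000334) in the authors' deposited table. Of AhR targets 5 of 8 rose and 0 fell in the authors' deposited table (the same numbers when adjusted over the list alone), CYP1B1 (log2 change 2.59) and CYP1A1 (2.06) the highest. Of p53 targets 11 of 21 rose and 5 fell in the authors' deposited table (12 and 5 when adjusted over the list alone), with CDKN1A (log2 change 3.44) and PLK3 (3.12). Kidney, adrenal and neural genes split 7 to 2 of 14 in the authors' deposited table (the same numbers when adjusted over the list alone), NEFH (log2 change 5.72) and NEFM (3.24) the highest. Cytoskeleton genes split 8 to 1 of 11 in the authors' deposited table (the same numbers when adjusted over the list alone), CCN2 (log2 change 2.46) and FLNA (1.59) the highest. CORO1A, of the blood list, had a log2 change of 3.49 and CDX2, of the colon list, one of 0.33 in the authors' deposited table.

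Termination and elongation factors split 2 higher to 12 lower of 29 at 12 h in the authors' deposited table (3 to 12 when adjusted over the list alone). HEXIM1 (log2 change 2.85) was higher, and the exosome nuclease EXOSC10 (-0.70) and the cleavage factor CPSF2 (-0.59) were lower in the authors' deposited table. Cell cycle genes split 11 to 3 of 29 (12 to 4 when adjusted over the list alone; CCNE1 1.53) and cholesterol synthesis genes 8 to 2 of 19 (9 to 3 when adjusted over the list alone; IDI1 1.03) in the authors' deposited table. Ribosomal protein genes split 7 to 0 of 43 (2 to 0 when adjusted over the list alone; RPS4X 0.31) in the authors' deposited table. Heat shock genes split 3 to 1 of 14 (HSPA6 1.64) and NF-κB targets 3 to 2 of 9 (TRAF1 1.26) in the authors' deposited table, with the same numbers when adjusted over the list alone. In the PP2A core, 0 of 4 passed in the authors' deposited table, also when adjusted over the list alone.

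At 12 h the authors' deposited table held 6404 of 14485 genes at an adjusted p under 0.05, 3170 higher and 3234 lower. With a log2 change of at least 1 in size the authors' deposited table held 1562, of which 1089 were higher. Among genes with a mean count of at least 100, 38.4% of those under 10 kb were higher and 13.3% lower, and of those over 100 kb, 11.8% were higher and 42.6% lower in the authors' deposited table. By cameraPR on the authors' deposited table, 9 of 20 lists differed at 12 h. Immediate early genes (adjusted p = 1.91e-47), Pol II snRNA (adjusted p = 2.59e-14), histones (adjusted p = 3.35e-10), and kidney, adrenal and neural genes (adjusted p = 1.61e-06) came first. The others by cameraPR were p53 targets (adjusted p = 0.00101), cytoskeleton genes (adjusted p = 0.00226), AhR targets (adjusted p = 0.00238), the interferon response (adjusted p = 0.00282) and Integrator subunits (adjusted p = 0.0251). With a correlation of 0.05 the Integrator list no longer passes (cameraPR adjusted p = 0.106). On ranks, cameraPR loses kidney, adrenal and neural genes (adjusted p = 0.240) and p53 targets (adjusted p = 0.0801). The integrated stress response and the unfolded protein response did not pass (cameraPR adjusted p = 0.0516 for each), and the Pol III small RNA list did not either (adjusted p = 0.248). On ranks, the unfolded protein response and the Pol III list pass (cameraPR adjusted p = 0.0352 for each), as do ribosomal proteins (adjusted p = 0.00934), and the integrated stress response does not (adjusted p = 0.259).

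**Figure D2:**
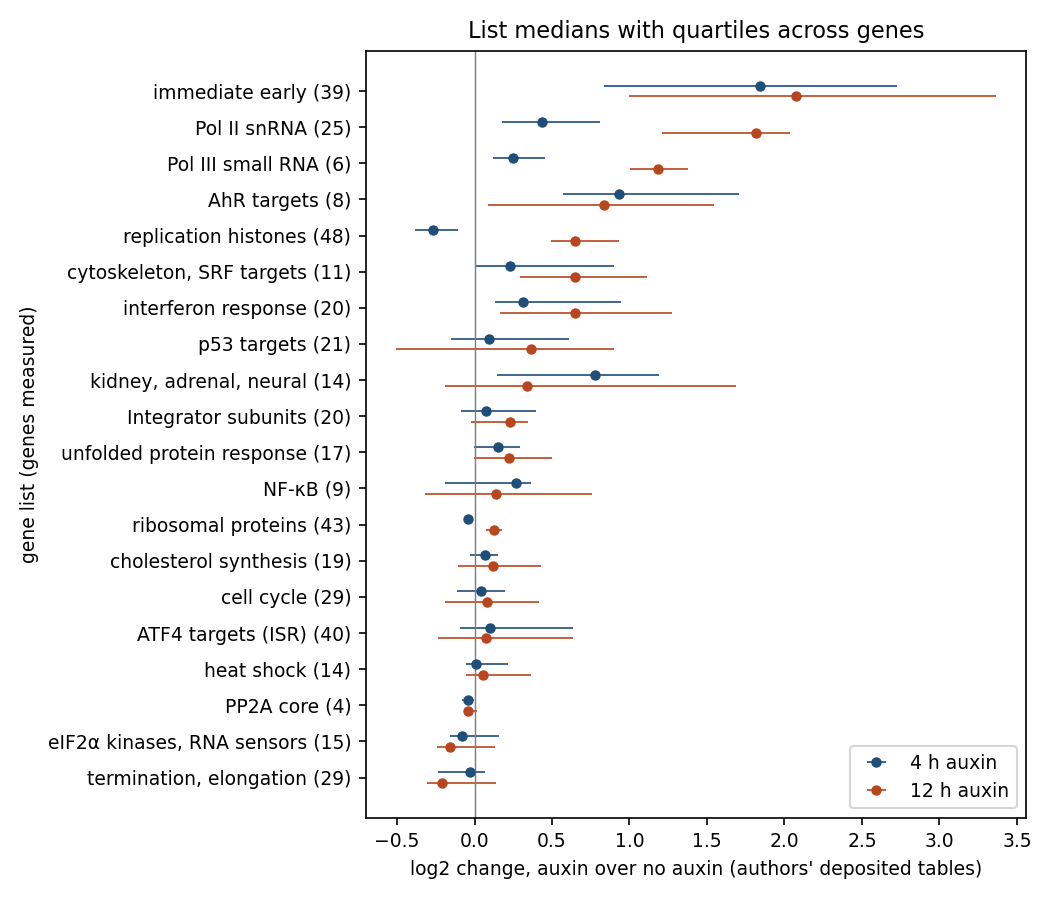
Median log2 change with auxin over without auxin for each fixed gene list at 4 h and 12 h (points, medians; bars, quartiles across genes; numbers in brackets, genes measured), from the authors' deposited table. Immediate early genes have the highest medians, 1.84 at 4 h and 2.08 at 12 h, and histones go from -0.27 to 0.65.

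The difference between the 12 h and the 4 h effect of auxin asks which responses differ between the 2 times, each a series of its own. Histone genes had the largest share of members that differ, with 45 of 48 genes having a higher effect at 12 h and 0 a lower one (46 when adjusted over the list alone, median difference 0.95 on the log2 scale). Examples are H2BC8 (difference 1.66), H2AC18 (1.34), H3C14 (1.29) and H3C12 (1.21). Pol II snRNA had a larger median difference, 1.14, with 20 of 25 higher and 0 lower (21 when adjusted over the list alone), RNU5F-1 (2.17) and RNU5B-1 (2.01) the highest. The effect on ETV5, a transcription factor downstream of growth factor signalling, was higher at 12 h by 2.91, and those on ARC (2.40), RPL3L (2.27) and NEFM (2.04) were higher too. Lower effects were those on TSPAN18 (-1.93), MAP2K6 (-1.65), PLEKHA7 (-1.52), RHBDL3 (-1.48) and IGFBP5 (-1.74). IGFBP5, a binding protein of insulin-like growth factor, had a log2 change of 0.76 at 4 h and -0.98 at 12 h in the authors' deposited table.

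The effect on DDIT3 was lower at 12 h than at 4 h (difference -0.61, Wald test adjusted p = 0.00447), and so were those on INTS6 (-0.51) and INTS2 (-0.46). Those on SESN2 (0.91), SLC7A5 (0.68), CEBPB (0.67), HERPUD1 (0.55), INTS4 (0.41) and INTS7 (0.39) were higher. Of 20 Integrator subunits, 2 effects were higher and 2 lower (3 and 2 when adjusted over the list alone). Of the integrated stress response list 5 effects were higher and 3 lower (the same numbers when adjusted over the list alone). The median of -0.14 lay at percentile 0.2 of the random lists matched on mean expression, and the mean was -0.07. The test by cameraPR was in the higher direction (adjusted p = 0.945). The differences for ATF4 (0.07), INTS1 (0.02), INTS11 (-0.19) and EIF2AK2 (-0.31) did not pass the Wald test. Of the interferon response list, 7 of 20 effects were higher at 12 h and 0 lower (the same numbers when adjusted over the list alone), with IRF7 (1.53), IFI6 (1.29) and IFITM1 (1.07). Of p53 targets 4 of 21 were higher and 0 lower (the same numbers when adjusted over the list alone), TNFRSF10B, a death receptor gene (1.31), and CDKN1A (1.02) among them. Immediate early genes had 11 of 39 higher and 2 lower (13 and 3 when adjusted over the list alone), and cytoskeleton genes 4 and 1 of 11 (the same numbers when adjusted over the list alone; FLNA 0.75). Of the Pol III small RNA list, 0 of 6 effects passed (3 higher when adjusted over the list alone). Ribosomal protein genes had 4 higher and 0 lower of 43 (1 and 0 when adjusted over the list alone; RPS4X 0.31). Kidney, adrenal and neural genes had 4 higher and 2 lower of 14 (4 and 4 when adjusted over the list alone), with a median difference of -0.23 and a mean of -0.08 but a test in the higher direction, where NEFM, NEFH (2.01) and NEFL (1.29) are the members with the highest differences named here. Signs also differed, with no call, for heat shock genes (median -0.01, mean 0.17), Integrator subunits (median -0.03, mean 0.00015) and termination and elongation factors (median 0.09, mean -0.01).

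A Wald test on the authors' log2 changes and implied standard errors called 2152 of 14460 genes at an FDR of 0.05, 916 with a higher and 1236 with a lower effect at 12 h. Opposite calls were seen for few genes, where 39 were higher at 4 h and lower at 12 h, and 58 lower at 4 h and higher at 12 h in the authors' deposited table. By cameraPR, 9 of 20 lists differed. Histones (adjusted p = 9.29e-73), Pol II snRNA (adjusted p = 2.84e-21), ribosomal proteins (adjusted p = 3.86e-05) and immediate early genes (adjusted p = 0.00360) came first. The others by cameraPR were p53 targets (adjusted p = 0.0211), the interferon response (adjusted p = 0.0215), kidney, adrenal and neural genes (adjusted p = 0.0219), cytoskeleton genes (adjusted p = 0.0490) and the Pol III small RNA list (adjusted p = 0.0495). Of these, histones, Pol II snRNA and ribosomal proteins pass with a correlation of 0.05, and the others do not (the lowest adjusted p of these is 0.0904). On ranks, cameraPR loses the interferon response (adjusted p = 0.0665), p53 targets and cytoskeleton genes (adjusted p = 0.165 for each) and kidney, adrenal and neural genes (adjusted p = 0.573, lower). The 4 h and 12 h libraries were normalized apart and the mean levels of the 2 series differ along GC content (Spearman rho 0.79 across genes). The difference therefore compares changes within each series and no levels between them. Each time with auxin is also a series of its own, so time and series cannot be told apart in these differences.

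**Figure D3:**
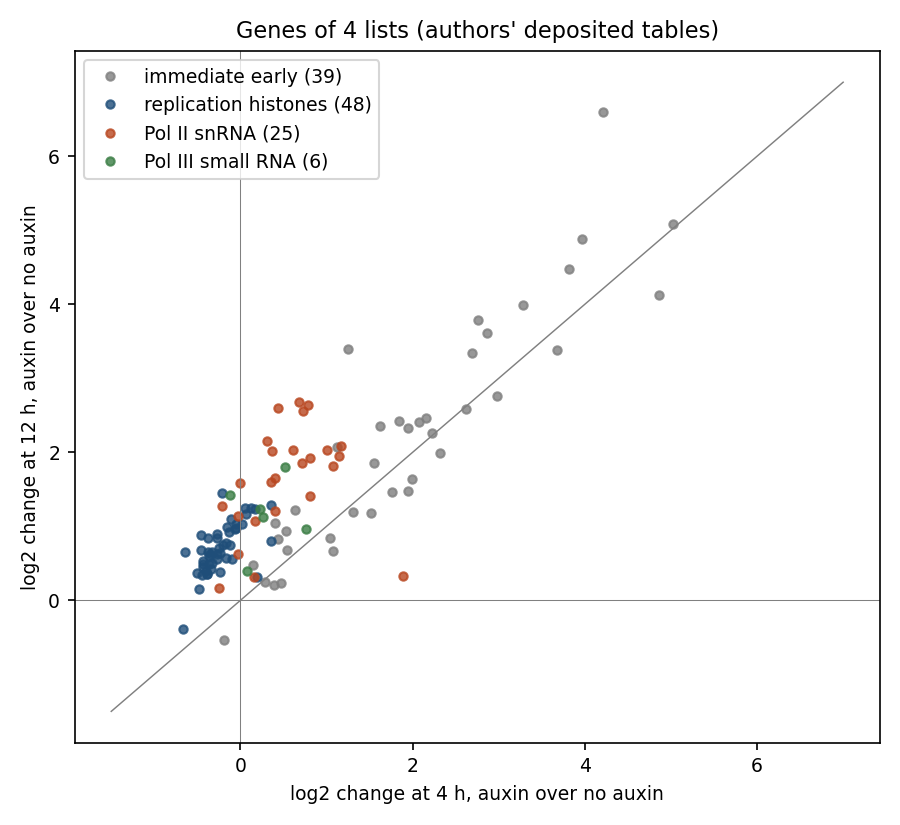
Log2 change with auxin over without auxin at 4 h (horizontal) and 12 h (vertical) for single genes of 4 fixed lists, from the authors' deposited table; the diagonal marks equal changes. Histone genes (median -0.27 at 4 h and 0.65 at 12 h) and Pol II snRNA (0.43 and 1.82) have medians above the diagonal.

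The calls of the 2 times were compared to ask how far the responses share genes. In the authors' deposited table, INTS6L, HEXIM1, CDKN1A, FOSB and CCDC80 are among 1959 genes higher at both times, where 608 would be shared by chance (odds ratio 20.8). Genes lower at both times numbered 1679 in the authors' deposited table, against 622 by chance (odds ratio 9.94), among them PAQR8, TFAP4 and CAMKK1. Across the 10700 genes with a mean count of 100 or more in both, Pearson's r of the log2 changes was 0.85 in the authors' deposited table; genes are not independent replicates. The 2 comparisons share no libraries. The 12 h direction was itself taken from the correlation of the 2 times. The sign of r, and that the shared calls go the same way, were therefore set in advance.

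The calls between untreated INTS1-AID and parental cells were compared with those of auxin. This asks whether the tagged line without auxin already differs in the genes that change with auxin. NQO1, ASNS, NEFL and H2BC15 were higher in untreated INTS1-AID than in parental cells, and each of these 4 also rose with auxin at 4 h in the authors' deposited table. ATF4 was also higher in INTS1-AID cells, but fell with auxin at 4 h in the authors' deposited table. CYP1B1 was lower in INTS1-AID cells and rose with auxin, by 2.02 on the log2 scale at 4 h in the authors' deposited table. Of 246 genes higher in INTS1-AID cells, 58 were higher at 4 h against 49.9 by chance (odds ratio 1.22, Fisher's exact test, two-sided p = 0.201), and 62 at 12 h against 55.1 by chance (odds ratio 1.17, p = 0.281) in the authors' deposited table. Of 49 genes lower in INTS1-AID cells, 3 were lower at 4 h against 10.2 by chance (odds ratio 0.246, two-sided p = 0.00760), and 14 at 12 h against 11.9 by chance (odds ratio 1.25, p = 0.504) in the authors' deposited table. With chromosome 5 genes dropped from the overlap but not from the fit, an alternative chosen after seeing the data, 14 of 37 higher genes were higher at 4 h in the authors' deposited table against 7.50 by chance (odds ratio 2.40, two-sided p = 0.0127). At 12 h, 13 of the 37 were higher in the authors' deposited table against 8.33 by chance. The odds ratio was 1.87 (Fisher's exact test, p = 0.0756). With chromosome 5 also left out of the adjustment, 9 higher genes pass in place of the 37. With a log2 change of at least 1 in both, 4 genes were shared with the authors' deposited table at 4 h (p = 0.0219) and 5 at 12 h (p = 0.0116), by Fisher's exact test. Pearson's r across 13293 genes between the 2 sets of log2 changes was 0.02 at 4 h and 0.09 at 12 h.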

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

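The tests on Pol II snRNA here were chosen only after the result was seen, as was the Wald test of the difference between times; comparisons that differ between 4 h and 12 h, and values from an assay that the comparisons above do not use, are given.

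Pol II snRNA had a higher auxin effect at 12 h than at 4 h, with a median difference of 1.14 on the log2 scale, and a median log2 change of 1.82 at 12 h in the authors' deposited table. Reads shared between near-identical copies are argued against as the whole cause, since RNU11, RNU12 and RNU4ATAC, each with 1 main copy, had a median log2 change of 1.92 at 12 h in the authors' deposited table and 3 of 3 passed. A gain of all RNA of up to 399 bases in the 12 h auxin libraries stays open. Other genes listed at that length with a mean count of at least 100 numbered 25. In the authors' deposited table their median log2 change was 0.14 and their upper quartile 0.63, below the Pol II lower quartile of 1.21. The listed length can be that of 1 short isoform of a longer mRNA, as with PPP2R1A (117 bases), so these genes cannot decide it. Over 191 such genes at any count, without the Pol III list, the median was 0.41 and the upper quartile 1.12 in the authors' deposited table. A gain of RNA under 200 bases, the length of the Pol II snRNA, stays open too. The 2 other genes listed at that length with a mean count of at least 100 are PPP2R1A (117 bases) and PDAP1 (120). Both are protein-coding genes, so they cannot stand for short RNA. The 5 Pol III genes of that length, at mean counts of up to 51, had a median log2 change of 1.24 in the authors' deposited table. Failed 3' end formation after INTS1 loss, the biological explanation, may account for it. At 12 h the Pol II and Pol III lists cannot be told apart with 25 and 6 genes (means 1.63 and 1.16, exact permutation test, two-sided p = 0.149). By TT-seq, an assay of newly made RNA, 14 of 25 Pol II snRNA genes were higher and 0 lower after 4 h of INTS1 degradation (median log2 change 0.46). Of the 6 Pol III genes 0 passed there (median -0.03), all in the authors' deposited table. Those libraries are not among the samples, and the lists were not tested against each other by TT-seq.

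The histone list had a median difference between 12 h and 4 h of 0.95 on the log2 scale. Histone genes were left out of the tests on short RNA above, and the cause of their difference was not tested. The Pol III small RNA list had a median difference of 0.93, with 0 of 6 members called (3 when adjusted over the list alone). Ribosomal protein genes had a median difference of 0.17. Immediate early genes had a median difference of 0.30. The SRF and cytoskeleton list also had a median difference of 0.30. The interferon response list had a median difference of 0.29, and p53 targets one of 0.082. Kidney, adrenal and neural genes had a median difference of -0.23 with a test in the higher direction, which is lower and not called on ranks. By the Wald test 2152 genes had effects that differ between the times.

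TT-seq, which labels newly made RNA, gave 3338 genes at an adjusted p under 0.05 after 4 h of INTS1 degradation in the authors' deposited table (1847 higher and 1491 lower of 13876). For INTS8, another Integrator subunit, TT-seq gave 1282 genes in the authors' deposited table (892 higher and 390 lower of 13592). The libraries behind these columns are not among the 17 samples.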

How the results depend on the processing

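The alternatives chosen only after the result was seen were edgeR with TMM, the removed GC trend, chromosome 5 left out, the authors' own calls, the Wald test, genes with a p listed as 0 left out of it, cameraPR, and camera without parental library 3. The chromosome 5 median stayed between 0.45 and 0.54 in the settings run for the untreated lines. Its 295 genes became 812 with DESeq2 on recovered reads, 1207 with the GC trend removed and 806 in the authors' deposited table; the cause was not tested. They became 11 at an FDR of 0.01 and 35 with a log2 change of at least 1, where fewer genes meet the criterion. With chromosome 5 left out of the adjustment they became 21 (9 higher and 12 lower). The main calls hold 37 higher and 49 lower genes off chromosome 5, so most of these pass only with chromosome 5 in the adjustment. With 1 library left out the count ran from 1 (without INTS1-AID replicate 1, or without parental replicate 1) to 2432 (without parental replicate 3); with the replicate block it was 6. Deviations from the group means correlate at -0.147, -0.0051 and -0.229 between libraries of the same replicate number, so no pairing shows. With 3 libraries per group and parental library 3 apart along GC content, pairing is not excluded. Of 30 called genes named for this comparison, 25 passed in each other fit run (pseudocounts, filters, edgeR, DESeq2, GC trend removed) and in the authors' deposited table. With the block 5 passed, and 1, 3 and 4 without INTS1-AID replicates 1, 2 and 3. Without parental replicates 1, 2 and 3 it was 1, 21 and 30, and 0 changed direction in these settings. INTS11, at -0.08, was 0.048 without parental replicate 3 (range -0.16 to 0.048 over libraries left out) and 0.092 with the GC trend removed; the cause was not tested.

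Calls at 4 h went from 5553 to 801 and at 12 h from 6404 to 1562 with a log2 change of at least 1, and to 600 and 1352 by the authors' own calls in the authors' deposited table. INTS1 at 4 h (-0.18) no longer passes at an FDR of 0.01 in the authors' deposited table. The 2152 genes that differ between times became 1295 at an FDR of 0.01 and 311 with a difference of at least 1. Lists that passed for the untreated lines went from 4 to 0 with an estimated correlation and to 8 with fry, which tests a list against no change and not against other genes. Of the 4, Pol II snRNA (fry adjusted p = 0.166) and histones (fry adjusted p = 0.130) are not among the 8. For the difference between times they went from 9 to 3 with a correlation of 0.05 and to 5 on ranks, and the cause was not tested. By the planned placing among random lists, 11 of 20 lists at 4 h, 12 at 12 h and 8 for the difference lay outside the central 95%. The odds ratio of genes higher in INTS1-AID cells and at 4 h was 4.28, and at 12 h 4.32, with a log2 change of at least 1, and 2.40 at 4 h and 1.87 at 12 h with chromosome 5 genes dropped from the overlap. The first 2 rest on 4 and 5 shared genes (Fisher's exact test, p = 0.0219 and 0.0116), and the last does not pass (p = 0.0756); the cause was not tested. For genes lower in both at 4 h it was 0 with a log2 change of at least 1, where 0.029 shared genes would be seen by chance, so it says nothing of depletion.

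No paired analysis was possible because values per library at 4 h and 12 h were not used here. For the same reason other size factors, library totals, own DESeq2 fits, filters, pseudocounts, a fit of each time alone, fly (dm6) scaling, each library left out, an estimated correlation and fry were not run for those comparisons.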

Other observations

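The count of other splits was planned; the tests on chromosome 5, with that of GC content, and on AhR targets were chosen only after the data were seen.

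Newly made RNA, by TT-seq, moved with the RNA levels at 4 h for most genes that rose the most. Of 757 genes with a rise of at least 1 on the log2 scale at 4 h in the authors' deposited table, 532 were higher by TT-seq after INTS1 degradation (70.3%) and 1 was lower. Histone genes had 21 of 48 lower and 0 higher by TT-seq in the authors' deposited table (median log2 change -0.56). Ribosomal protein genes had 26 of 43 lower and 0 higher by TT-seq in the authors' deposited table (median log2 change -0.31), where 3 were lower at 4 h by RNA level. Across genes with a mean of at least 100 in both, Pearson's r between TT-seq and RNA changes at 4 h was 0.89 in the authors' deposited table; genes are not independent replicates.

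Long non-coding RNA rose more often than it fell, 212 against 19 of 1353 at 4 h and 281 against 51 of 1360 at 12 h in the authors' deposited table. Across genes with a mean count of at least 100, log2 change and gene length had a Spearman rho of -0.21 at 4 h and -0.30 at 12 h in the authors' deposited table.

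Genes of chromosome 5 were higher in untreated INTS1-AID than in parental cells, with a median log2 change of 0.52. GC content together with parental library 3 is argued against as the whole cause, since the median is 0.45 with each library's GC trend removed, where the highest other chromosome is at 0.0094. A few genes or 1 segment are argued against too, since the lowest of 18 windows of 10 Mb with at least 5 genes has a median of 0.28, above the highest median of another whole chromosome (0.05); a window with 3 genes has 0.16. A difference in copy number of chromosome 5 between the lines is a candidate explanation: the median of 0.52 lies between 0.32 and 0.58, the log2 ratios for 1 copy gained over 4 or over 2, and the lowest INTS1-AID library (0.51) is above the highest parental one (0.06). DNA was not analysed here, and whether such a gain came with the tag or with the growth of a clone was not tested.

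The 6 untreated libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 295 genes by limma and the highest other gave 0. The 1 split of the 10 that reached 295 is the real one.

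AhR targets were higher with auxin, with a median log2 change of 0.93 at 4 h in the authors' deposited table. Auxin is an indole, and indoles can bind AhR, so auxin itself may act on these genes apart from the loss of Integrator. If so, AhR targets would rise by TT-seq with INTS8 more than their INTS1 change foretells. This assumes the same auxin in the INTS8 cells, whose libraries are not among the samples. The 8 genes departed from the line of INTS8 on INTS1 changes by 0.28. That is percentile 97.3 among genes of like INTS1 change and 99.4 among genes of like signal. The first falls short of the rule set for the test, so the test leaves the question open. An earlier form of this test, with a signal of at least 20 and 6 genes, gave 0.46 and percentile 100; it was changed after its result was seen because it left out 2 members and did not match on the INTS1 change. Auxin and the loss of INTS1 cannot be told apart for these genes, since 0 libraries of auxin-treated parental cells are among the samples.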
